A study of Mus musculus with 75 samples.

How the data were processed

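Gene expression was measured on 75 one-colour arrays of biotin-labelled cRNA from mouse medulloblastoma allografts, 1 array per sample. The deposited values are intensity values, 1 per probe set, and the submitters' processing notes name RMA without its settings. All values were above 0 (0.0166 to 99.9) and every array had a mean of 1, so they were read as a linear scale with each array scaled to that mean. The plan made before the data were examined had assumed log2 values, and log2 was therefore taken first, without a pseudocount. The genome build is not stated. The number of arrays limits the precision, and total counts do not apply.

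Of 43681 probe sets 30342 carried 1 gene symbol and 13339 none, and the latter were left out. Symbols were brought up to date with the RefSeq gene table, by accession for 15257 probe sets and by symbol or synonym for the others, and 53 unmatched symbols were kept as given. Where a gene had several probe sets (6060 genes) the one with the highest mean over all arrays was used, which left 21552 genes, with no filter on dim genes.

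Samples were grouped by schedule, dose and time from the labels into 19 groups. All 75 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with 56 residual degrees of freedom and 3.37 prior degrees of freedom. Moderated t tests were made for 11 treatment comparisons with vehicle of the same schedule and time, for the 2 doses at each time, for differences between effects and for multiple against single dosing with vehicle. A moderated F test compared vehicle arrays across the 5 single-dose times. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. The group with 1 array was not tested in the reported fit, and its list medians were placed among 10000 random lists matched on mean level.

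A set of 30 gene lists of pathways, cell states and cell types was written before the data were examined. Lists with at least 5 measured genes were tested with camera in limma at its preset correlation of 0.01, with adjustment over the lists of a comparison. In all 103 of 319 list tests were called, and 28 of these held when camera estimated the correlation within each list. Beside each list the number of called genes is given with adjustment over all genes and with adjustment over the list alone. The mean log2 of 4 hedgehog target genes per array, and differences between list means, were compared by exact two-sided permutation tests with adjustment over 11 comparisons.

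Genes were named by a rule set before the data were examined. It took genes of the pathway (among them Gli1, Ptch1, Hhip, Sfrp1, Mycn, Ccnd1, Ccnd2 and Smo) in every treatment comparison. Among genes with an adjusted p under 0.05 in limma whose treated samples all lay outside the vehicle range it took the 10 largest rises and 10 largest falls for 80 mpk at 6, 12 and 24 h and for multiple doses at 36 h, and 4 of each for the others, leaving out genes with placeholder names. It also took up to 4 members of a list with the smallest adjusted p, and for vehicle comparisons the clock genes and the 5 genes with the smallest adjusted p. The separation of the largest rises and falls from vehicle is thus fixed by the rule and adds no support.

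The alternatives chosen before the data were examined were the mean of all probe sets of a gene, a filter on dim genes (14368 genes left), a second quantile normalization, a variance prior with trend and robust fitting, array weights, replicate number as a block, the muscle and fibroblast list means as covariates, only the groups compared in the fit, and leaving out each array in turn. The same plan held the estimated correlation and the fry test for lists, and Gli1 alone for the mean of 4 target genes. The 2 alternatives chosen after seeing the data were 4 list means as covariates and leaving out the 22 arrays with a muscle list mean above 0 on the log2 scale, which left 53 arrays. The fit was tested on simulated data with known changes. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.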

Results

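The series followed gene expression in mouse medulloblastoma allografts after dosing with MK4101, which the labels describe as an inhibitor of the sonic hedgehog (SHH) pathway. The tumours came from Ptch1+/- mice and were grown in nude CD1 mice. Ptch1 encodes the receptor that holds the pathway off, and its loss leaves the pathway on. A total of 75 arrays fell into 19 groups. After a single dose (QD) 61 arrays covered 1, 6, 12, 24 and 36 h. The vehicle groups held 5, 5, 4, 5 and 3 arrays at these times. The 40 mpk groups held 4, 5, 3, 4 and 3 arrays and the 80 mpk groups 5, 3, 4, 4 and 4, where mpk is the dose unit of the labels (mg per kg). Multiple dosing (BID) gave 14 arrays. These were 4 vehicle arrays and 1 array of 80 mpk at 24 h, and 5 vehicle arrays and 4 arrays of 80 mpk at 36 h. The median scaled intensity of an array lay between 0.109 and 0.131, and the lowest correlation between 2 arrays was 0.941. The number of arrays in a group limits the precision of every difference. The labels do not say whether arrays of a group came from separate animals, so the p-values measure the spread between samples. Differences are log2 fold changes of treated minus vehicle with their standard error (SE). A gene counts as higher or lower where its adjusted p was under 0.05.

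An early response was sought 1 h after dosing. Gli1, the transcription factor induced by the pathway and its usual readout, stood at 2.60 (geometric mean scaled intensity, n = 5) with 80 mpk and 2.41 (n = 5) with vehicle, a difference of 0.11 ± 0.19 (adjusted p = 0.951). With 40 mpk (n = 4) the difference was 0.17 ± 0.21 (adjusted p = 0.811). Ptch1 differed by 0.09 ± 0.10 at 80 mpk (adjusted p = 0.91). limma called 0 genes at either dose, with 1325 genes at an unadjusted p under 0.05 for 80 mpk and 2290 for 40 mpk, against 1078 by chance. At 40 mpk 4 lists were called by camera without a called member. Each of them had an adjusted p = 0.832 with an estimated correlation. Leaving out replicate 2 of the 40 mpk arrays gave 43 genes and leaving out replicate 1 gave 1. Leaving out replicate 4 of the vehicle arrays gave 1 gene at 80 mpk.

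**Figure D1:**
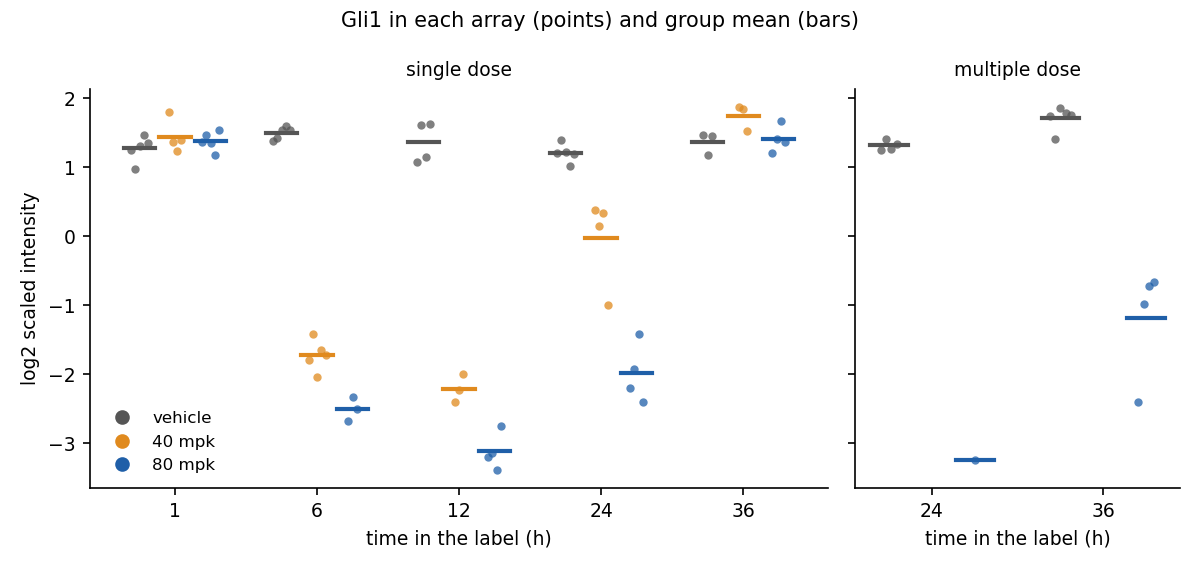
Gli1 in each array as log2 scaled intensity (points) with the mean of each group (bars), by the time in the label, dose and schedule. The means of the 80 mpk arrays were 0.176 at 6 h and 0.115 at 12 h on the linear scale, and 2.66 at 36 h, where vehicle arrays stood at 2.57.

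At 6 h the hedgehog targets were lower with 80 mpk. Gli1 fell 15.97-fold, from 2.82 in vehicle arrays (n = 5) to 0.176 (n = 3), a change of -4.00 ± 0.22 (adjusted p = 3.73e-21). All 3 treated arrays lay below every vehicle array. Ptch1 changed by -1.35 ± 0.12 (adjusted p = 7.01e-13) and Hhip, a decoy receptor for hedgehog ligands, by -1.36 ± 0.26 (0.000411). Ccnd1 (cyclin D1) changed by -0.61 ± 0.13 (0.00184), and all 3 genes were lower in all 3 treated arrays than in any vehicle array. Sfrp1, a secreted Wnt antagonist, differed by -0.55 ± 0.17 and did not pass the test (adjusted p = 0.0818). Nor did Mycn at -0.02, Ccnd2 at -0.28 or Smo, the target of such inhibitors, at -0.13. Of 17 measured hedgehog target genes 6 were lower and 0 higher (9 and 2 adjusted over the list alone). Camera gave the list an adjusted p = 5.76e-12, which held with an estimated correlation (0.00324). Boc, a co-receptor, changed by -1.03 ± 0.16 and Gli2, a transcription factor of the pathway, by -1.01 ± 0.17. Other large falls were in Gdf10 (-2.19 ± 0.31), Pdgfa (-2.10 ± 0.14), Sox18 (-2.05 ± 0.13), Clic6 (-2.01 ± 0.20) and Wif1, an inhibitor of Wnt ligands (-1.96 ± 0.24). Next came Hmox1 (-1.83 ± 0.46), Bcl11b (-1.81 ± 0.16), Ackr3 (-1.68 ± 0.36) and Rgma (-1.67 ± 0.17).

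Rises at 6 h were led by Rgs1 (2.31 ± 0.45), Igfbp5, which binds insulin-like growth factors (1.20 ± 0.22), Ddit4, an inhibitor of mTOR signalling (1.04 ± 0.17), and Dmrta1 (1.04 ± 0.16). They were followed by Cemip (0.99), Kcnj6 (0.97), Rasd2 (0.89), Neurod6 (0.89), Nrn1 (0.87) and Barhl1 (0.86 ± 0.10). In all of these genes and the large falls every treated array lay outside the vehicle range, as the naming rule required. Of 17 granule neuron progenitor genes 5 were higher and 0 lower (9 and 1 adjusted over the list alone; list adjusted p = 1.05e-07, and 0.0274 with an estimated correlation). They included Barhl1, Meis1 (0.50 ± 0.09), Lhx9 (0.52 ± 0.11) and Zic1 (0.38 ± 0.10). Among 25 G1/S and DNA replication genes Ccne2 (-0.73 ± 0.17) and Mcm3 (-0.49 ± 0.13) were lower. The list had 11 lower adjusted over the list alone and a list median of -0.23. That list (adjusted p = 4.35e-14), the ribosome biogenesis list with 2 of 17 lower (6.76e-08) were both called. So was the hypoxia list (6.76e-08) with 1 of 15 lower, Hk2 at -1.41 ± 0.12, and all 3 lists had an adjusted p = 0.0952 with an estimated correlation. Neuronal differentiation genes had 2 of 26 higher (8 adjusted over the list alone; list adjusted p = 3.45e-05). That list had an adjusted p = 0.224 with an estimated correlation. Calls of the lists of pathway components, endothelial markers, muscle markers and sterol synthesis genes had an adjusted p = 0.321 to 0.712 with an estimated correlation. They were lost without treated replicate 3 (0.215), vehicle replicate 1 (0.519), treated replicate 1 (0.962) and vehicle replicate 1 (0.315) in that order. In all 378 genes were called at 6 h, 124 higher and 254 lower, and 60 of them by 2-fold or more. Leaving out replicate 2 or 3 of the treated arrays gave 243 and 236 genes. Hmox1 (adjusted p = 0.237), Ackr3 (0.112) and Neurod6 (0.135) lost their calls without replicate 2. Hmox1 (0.145) and Neurod6 (0.0569) lost them also without replicate 3, and Hmox1 without replicate 2 of the vehicle arrays (0.0568). The granule neuron progenitor count was 3 without treated replicate 2 or 3 or vehicle replicate 1 or 5. The neuronal count was 1 and 0 without treated replicates 2 and 3 and 4 without vehicle replicate 3. The ribosome biogenesis count was 1, 1 and 0 without treated replicates 1, 2 and 3. The G1/S count was 0 or 1 without any treated array or vehicle replicate 3, 4 or 5 and 4 without vehicle replicate 1. Skeletal muscle genes stood out in 2 of the 3 treated and 1 of the 5 vehicle arrays (mean log2 above 0). Without all such arrays 1 treated array was left, in which Hhip differed by -1.56. That fit took its spread from other groups, so it is not read as a test.

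At 12 h Gli1 was lower still relative to vehicle, at 0.115 (n = 4) against 2.57 (n = 4), a 22.3-fold fall (-4.48 ± 0.22, adjusted p = 2.08e-24). Ptch1 changed by -1.55 ± 0.12 (3.38e-16), Hhip by -1.42 ± 0.25 (2.34e-05) and Ccnd1 by -1.01 ± 0.12 (4.26e-09). Each of these was lower in all 4 treated arrays than in any vehicle array. Sfrp1 (-0.36, adjusted p = 0.177), Ccnd2 (0.04), Mycn (0.10) and Smo (0.04) did not pass the test. Hedgehog target genes had 7 of 17 lower and 1 higher (9 and 2 adjusted over the list alone; list adjusted p = 1.58e-07, and 0.0243 with an estimated correlation). Genes of DNA replication fell as a group. Of 25 G1/S genes 22 were lower (25 adjusted over the list alone), with a median of -0.70 and a list adjusted p = 5.27e-40 (0.002 with an estimated correlation). They included Ccne2, cyclin E2 (-1.77 ± 0.17), Mcm3 (-1.25 ± 0.13), Mcm2 (-1.19 ± 0.13) and Mcm4 (-1.15 ± 0.10), subunits of the replicative helicase. Of 25 G2/M and mitosis genes 1 was higher and 0 lower, and that list was not called. The mean of the G1/S genes minus that of the G2/M genes differed from vehicle by -0.40 at 6 h (exact two-sided permutation p = 0.0179, adjusted 0.0449 over 11 comparisons). At 12 h it differed by -0.85 (exact two-sided permutation p = 0.0286, adjusted 0.0449). Both are the smallest p that these group sizes allow. At 1 h it differed by -0.09 with 80 mpk and -0.08 with 40 mpk (each exact two-sided permutation p = 0.0238, adjusted 0.0449 over 11 comparisons), although limma called 0 genes there. Both doses were set against the same 5 vehicle arrays (mean -0.39). The treated means (-0.48 and -0.47) lay within the spread of other vehicle groups (-0.48 at 6 h, -0.33 at 12 h and -0.54 with multiple dosing at 36 h). An onset at 1 h is therefore not shown. At 24 h and 36 h with 80 mpk it differed by 0.11 and 0.21 and did not pass (adjusted 0.194 and 0.252 by the same exact test).

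Granule neuron progenitor genes had 8 of 17 higher at 12 h (8 adjusted over the list alone; list adjusted p = 3.14e-08, and 0.0193 with an estimated correlation). Barhl1 rose by 1.29 ± 0.10, Meis1 by 0.75 ± 0.09 and Atoh1, the transcription factor of granule neuron progenitors, by 0.56 ± 0.12 (log2 fold changes). Neuronal differentiation genes had 8 of 26 higher (12 adjusted over the list alone; list adjusted p = 1.7e-07), including Stmn2 (0.82 ± 0.11) and Cntn2 (0.92 ± 0.18). The list had an adjusted p = 0.0709 with an estimated correlation. The largest rises were in Dmrta1 (2.08 ± 0.15), Igfbp5 (2.0 ± 0.21), Chrna3, a nicotinic receptor subunit (1.51 ± 0.22). They were followed by Rec8 (1.39), Robo2 (1.35), Irs4 (1.29), Nol4l (1.28), Tprn (1.21) and Cemip (1.19). Large falls besides Gli1 were in Ptgs2, which encodes cyclooxygenase-2 (-2.82 ± 0.56, with a vehicle SD of 2.0), Wif1 (-2.62 ± 0.23) and Tmem28 (-2.37). Further falls were in Dcpp1 (-2.31), Pdgfa (-2.25 ± 0.14), Dcpp2 (-2.19), Gdf10 (-2.18), Fam155a (-2.13) and Kank1 (-2.10). In each of these genes every treated array lay outside the vehicle range, as the naming rule required.

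Immediate early genes had 10 of 16 lower at 12 h (12 adjusted over the list alone, median -0.88, list adjusted p = 4.23e-11), with Fosl2 at -1.99 ± 0.20 and Jun at -0.83 ± 0.10. Hypoxia response genes had 8 of 15 lower (11 adjusted over the list alone, median -0.57, list adjusted p = 1.31e-08). Among them were the glycolytic enzyme Hk2 at -1.62 ± 0.12 and Egln3 at -1.58 ± 0.32. Ribosome biogenesis and Myc target genes had 8 of 17 lower (14 adjusted over the list alone; list adjusted p = 2.93e-09). Each of these 3 lists had an adjusted p = 0.0465 with an estimated correlation. In all 2120 genes were called, 829 higher and 1291 lower (39.1% higher, and 50.4% after a second quantile normalization). Of these 188 changed by 2-fold or more. Without replicate 3 of the vehicle arrays 5 immediate early, 4 hypoxia and 5 neuronal differentiation genes were called. A call of the xenobiotic response list (3 of 13 lower, adjusted p = 0.0493, and 0.0709 with an estimated correlation) was lost at 0.317.

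**Figure D2:**
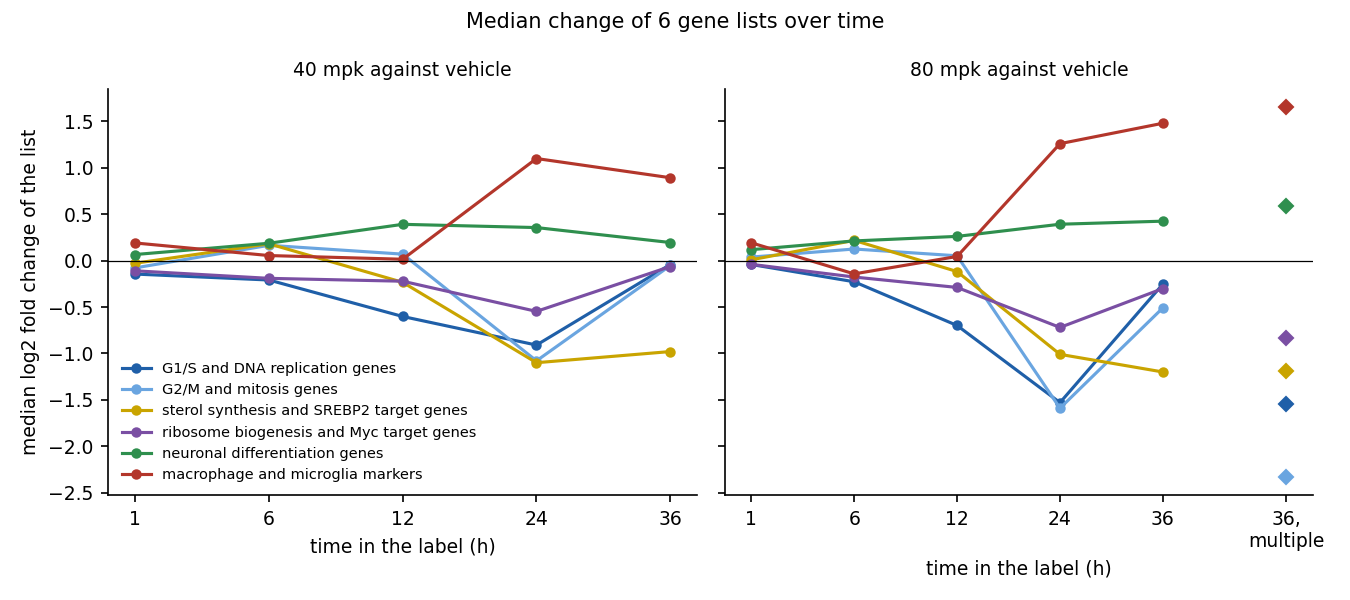
Median log2 fold change against vehicle of 6 gene lists by the time in the label, for single doses of 40 and 80 mpk (lines) and multiple doses of 80 mpk at 36 h (diamonds). With 80 mpk the G1/S median was -0.70 at 12 h, -1.53 at 24 h and -0.25 at 36 h, while the sterol synthesis median was -1.01 at 24 h and -1.20 at 36 h.

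At 24 h the tumours showed a broad loss of cell cycle transcripts with 80 mpk. All 25 G1/S genes were lower (25 adjusted over the list alone, median -1.53, list adjusted p = 5.54e-36, and 0.0045 with an estimated correlation). They were led by the replication factors Cdc45 (-1.96 ± 0.13) and Mcm10 (-1.93 ± 0.13) and by Rrm1, a subunit of ribonucleotide reductase (-1.41 ± 0.09). Of 25 G2/M and mitosis genes 24 were lower (25 adjusted over the list alone, median -1.59, list adjusted p = 3.59e-37, and 0.0095 with an estimated correlation). Among these were the mitotic kinases Bub1 (-1.92 ± 0.11) and Cdk1 (-1.71 ± 0.10). All 4 treated arrays had list means below every vehicle array for both. Gli1 was 9.11-fold lower, at 0.253 (n = 4) against 2.30 (n = 5), a change of -3.19 ± 0.21 (adjusted p = 1.16e-19). Ptch1 changed by -1.39 ± 0.11 (2.17e-16), Hhip by -1.38 ± 0.24 (2.57e-06) and Ccnd1 by -0.88 ± 0.12 (6.76e-09). Ccnd2, cyclin D2, rose by 0.74 ± 0.11 (2.28e-07), and all 5 genes lay outside the vehicle range in all 4 arrays. Sfrp1 (0.06), Mycn (0.19, adjusted p = 0.132) and Smo (-0.25, adjusted p = 0.102) did not pass the test. Hedgehog target genes had 7 of 17 lower and 1 higher (7 and 1 adjusted over the list alone; list adjusted p = 0.000736). That list had an adjusted p = 0.19 with an estimated correlation.

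All 14 sterol synthesis genes were lower at 24 h (14 adjusted over the list alone, median -1.01, list adjusted p = 4.19e-16, and 0.0147 with an estimated correlation). They included the cholesterol pathway enzymes Idi1 (-2.45 ± 0.16), Fdps (-2.34 ± 0.23), Msmo1 (-2.30 ± 0.16) and Cyp51 (-2.04 ± 0.13). All 17 ribosome biogenesis and Myc target genes were lower (17 adjusted over the list alone, median -0.72, list adjusted p = 2.84e-17, and 0.00599 with an estimated correlation). Examples were Nop56 (-1.24 ± 0.08) and Nolc1 (-1.15 ± 0.09). Both list means were below every vehicle array in all 4 treated arrays. The largest single fall was in Wif1, which was 27.8-fold lower (-4.80 ± 0.22, adjusted p = 7.78e-26). Further falls, each with every treated array below the vehicle range by the naming rule, were in Dcpp1 (-2.87), Fam155a (-2.61), Dcpp2 (-2.59), Tmem28 (-2.57), Sowaha (-2.47) and Syt13 (-2.43).

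Lists of neuronal and of some host cell genes were called higher at 24 h without an allowance for correlation. Neuronal differentiation genes had 14 of 26 higher and 2 lower (17 and 3 adjusted over the list alone; 0 or 1 lower without any of the treated arrays or vehicle replicates 2 to 5; list adjusted p = 7.85e-05). Stmn2 rose by 1.10 ± 0.11, the migration gene Dcx by 1.28 ± 0.18 and Cntn2 by 1.22 ± 0.17 (log2 fold changes). Granule neuron progenitor genes had 7 of 17 higher and 1 lower (8 and 1 adjusted over the list alone; 0.00406). Both had an adjusted p = 0.261 with an estimated correlation. Macrophage and microglia markers had 12 of 14 higher (12 adjusted over the list alone, median 1.26, list adjusted p = 4.4e-05). The list, with Cd68 at 1.81 ± 0.34 and Csf1r at 1.12 ± 0.25, had an adjusted p = 0.417 with an estimated correlation. Fibroblast and matrix markers had 11 of 13 higher (12 adjusted over the list alone, median 1.11, 0.000687). That list, with Col1a2 at 1.17 ± 0.29, had an adjusted p = 0.455 with an estimated correlation. Endothelial markers had 10 of 12 higher (10 adjusted over the list alone, median 0.90, 0.000197). These, with Cldn5 at 2.04 ± 0.39, had an adjusted p = 0.397 with an estimated correlation. Beside these groups, 2 of the 4 treated and 1 of the 5 vehicle arrays were rich in muscle transcripts. With the muscle and fibroblast list means as covariates the macrophage and microglia markers had an adjusted p = 0.0506 and the endothelial list 0.0656. That fit holds no test of the fibroblast list, whose own mean was a covariate. Genes of the p53 response and cell death had 7 of 18 higher and 1 lower (9 and 1 adjusted over the list alone; 0.00135). This list, with Trp53inp1 at 1.80 ± 0.12 and the cell death gene Bbc3 at 0.65 ± 0.09, had an adjusted p = 0.0799 with an estimated correlation.

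The largest rises at 24 h were in Lcn2 (3.16 ± 1.30), Scara5 (2.78 ± 0.69), the fat cell hormone Adipoq (2.76 ± 0.84) and Igfbp5 (2.63 ± 0.20, adjusted p = 3.22e-17). They were followed by C1qtnf3 (2.61), Abca8a (2.57), Ogn (2.53), Steap4 (2.49), the cholesterol exporter Abca1 (2.45 ± 0.33, 5.47-fold, adjusted p = 1.14e-08) and Scn7a (2.45). By the naming rule each lay above the vehicle range in all 4 arrays. Scara5, Adipoq, C1qtnf3, Abca8a, Ogn and Steap4 lost their calls with muscle and host list means as covariates. Adipocyte markers had 2 of 9 higher (8 adjusted over the list alone; list adjusted p = 0.0349), and that list had an adjusted p = 0.686 with an estimated correlation. Glucocorticoid response genes had 7 of 12 higher and 1 lower (8 and 1 adjusted over the list alone; 0.0134), with Klf9 at 1.0 ± 0.17 and Fkbp5 at -0.98 ± 0.08. The list had an adjusted p = 0.36 with an estimated correlation. In all 7095 genes were called, 3800 higher and 3295 lower (53.6% higher, and 43.4% after a second quantile normalization). Of these 1300 changed by 2-fold or more. Leaving out replicate 1 of the treated arrays ended the calls of Adipoq (adjusted p = 0.0571), Lcn2 (0.201) and the adipocyte list (0.144). Replicate 2 ended that of Lcn2 (0.113), replicate 3 that of C1qtnf3 (0.0667), and each of the 5 vehicle arrays that of Lcn2 (0.0577 to 0.0731).

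At 36 h after a single dose the hedgehog targets were back near vehicle. Gli1 stood at 2.66 (n = 4) against 2.57 (n = 3), a difference of 0.05 ± 0.23 (adjusted p = 0.936). Ptch1 differed by -0.24 ± 0.12 (0.228), Hhip by -0.03 ± 0.27 (0.972) and Ccnd1 by -0.20 ± 0.13 (0.401). Sfrp1 differed by 0.09 (0.818), Mycn by -0.01 and Smo by -0.34 (0.0959). All 4 treated arrays lay below every vehicle array for Ccnd1 and for Smo, and 2 of 4 for Ptch1. Ccnd2 was higher by 0.80 ± 0.13 (adjusted p = 7.89e-06, all 4 arrays above vehicle). Hedgehog target genes had 4 of 17 lower and 1 higher (5 and 1 adjusted over the list alone, and 2 lower without vehicle replicate 1 or 3 or treated replicate 4), and that list was not called (adjusted p = 0.117) but was called lower without vehicle replicate 2 (0.0259). The 14 sterol synthesis genes were all lower (14 adjusted over the list alone, median -1.20, list adjusted p = 7.76e-36, and 0.000215 with an estimated correlation). Msmo1 stood at -2.11 ± 0.18, Fdps at -2.09 ± 0.26, Idi1 at -2.02 ± 0.18 and Cyp51 at -1.58 ± 0.15. Macrophage and microglia markers had 12 of 14 higher (12 adjusted over the list alone, median 1.48, list adjusted p = 1.32e-12), with Cx3cr1 at 1.46 ± 0.24 and Csf1r at 1.41 ± 0.29. All 4 treated arrays had list means above every vehicle array. The list had an adjusted p = 0.166 with an estimated correlation. Fibroblast and matrix markers had 1 of 13 higher (1 adjusted over the list alone, median 0.69, list adjusted p = 0.000376). They had an adjusted p = 0.562 with an estimated correlation. Of the 14 skeletal muscle markers limma called 0 (0 adjusted over the list alone, median 2.08, list adjusted p = 0.0386). They had an adjusted p = 0.744 with an estimated correlation and 0.386 without treated replicate 1. G2/M genes had 17 of 25 lower (23 adjusted over the list alone, median -0.51, list adjusted p = 8.11e-14), such as Ccnb2, cyclin B2 (-0.87 ± 0.15). This list had an adjusted p = 0.2 with an estimated correlation. G1/S genes had 4 of 25 lower (8 adjusted over the list alone, median -0.25, 1.47e-05). Their list had an adjusted p = 0.415 with an estimated correlation.

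**Figure D3:**
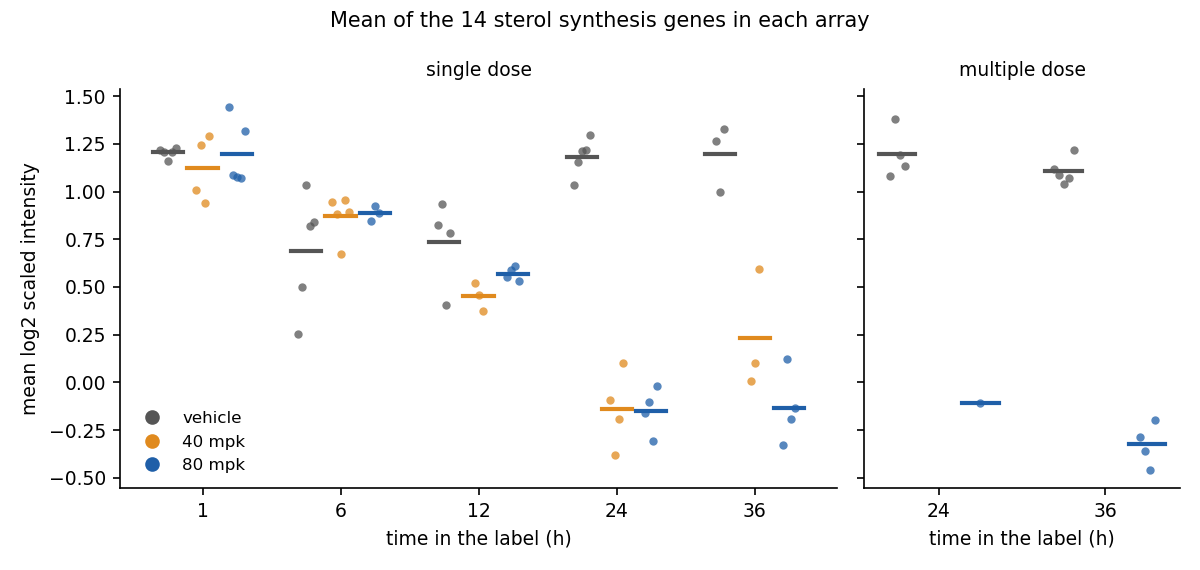
Mean log2 scaled intensity of the 14 sterol synthesis genes in each array (points) with the mean of each group (bars), by the time in the label, dose and schedule. All 4 arrays of 80 mpk lay below every vehicle array at 24 h and at 36 h, and so did the 3 arrays of 40 mpk at 36 h.

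Neuronal differentiation genes had 12 of 26 higher at 36 h (14 and 1 lower adjusted over the list alone, list adjusted p = 9.55e-11). The list, with Stmn2 at 1.21 ± 0.12 and the microtubule gene Mapt at 1.23 ± 0.17, had an adjusted p = 0.0643 with an estimated correlation. Ribosome biogenesis genes had 10 of 17 lower (12 adjusted over the list alone; 1.05e-06), and the list had an adjusted p = 0.166 with an estimated correlation. Hypoxia genes had 6 of 15 lower (7 adjusted over the list alone; 0.0001), Vegfa at -1.27 ± 0.32. That list had an adjusted p = 0.269 with an estimated correlation. The largest rises were in Gbp8 (3.65 ± 0.61), Clec7a (2.92 ± 0.49) and Serpina3g (2.86 ± 0.59) and in the iron exporter Slc40a1 (2.82 ± 0.45). The largest falls were in Cbln4 (-2.26 ± 0.24), Ssu2 (-2.13 ± 0.19), Msmo1 and Fdps, each outside the vehicle range in all 4 arrays by the naming rule. In all 2341 genes were called, 1126 higher and 1215 lower, 353 by 2-fold or more. Without vehicle replicate 1 the count was 1357, with 7 macrophage markers, 9 G2/M, 5 ribosome biogenesis, 3 hypoxia and 1 G1/S genes. Without vehicle replicate 3 it was 1275, with 6 macrophage markers, 4 ribosome biogenesis, 2 hypoxia and 1 G1/S genes. Without treated replicate 1 it was 1300, with 6 G2/M, 4 ribosome biogenesis and 1 G1/S genes, and without treated replicate 3 the G1/S count was also 1. Muscle-rich arrays were 1 of 4 treated and 0 of 3 vehicle. Without all such arrays 1186 genes were called.

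Multiple doses of 80 mpk kept the hedgehog targets low at 36 h. Gli1 was 7.46-fold lower, at 0.438 (n = 4) against 3.27 (n = 5), a change of -2.90 ± 0.21 (adjusted p = 1.4e-18). Ptch1 changed by -1.68 ± 0.11 (3.58e-20), Hhip by -1.26 ± 0.24 (1.08e-05) and Ccnd1 by -1.31 ± 0.12 (1.11e-14). Smo changed by -0.51 ± 0.12 (0.000338) and Ccnd2 by 0.83 ± 0.11 (1.05e-08), and all 6 genes lay outside the vehicle range in all 4 arrays. Mycn was lower by -0.29 ± 0.10 (adjusted p = 0.0162, 1 of 4 arrays below vehicle). That call was lost without treated replicate 1 (0.126) or vehicle replicate 2 (0.079) or 4 (0.0623). The change in Mycn was 0.00208 with the muscle and fibroblast covariates and 0.0609 with 4 list covariates, so its direction did not hold. Sfrp1 differed by 0.28 (0.158). All 25 G1/S genes (25 adjusted over the list alone, median -1.54, list adjusted p = 3.52e-30) and all 25 G2/M genes (25 adjusted over the list alone, median -2.33, 1.04e-44) were lower, both with an adjusted p = 0.00462 with an estimated correlation. Among them were Cdk1 (-2.33 ± 0.10), Bub1 (-2.47 ± 0.11), thymidylate synthase Tyms (-1.78 ± 0.11) and thymidine kinase Tk1 (-2.19 ± 0.13). The mean of the G1/S genes minus that of the G2/M genes differed from vehicle by 0.75 (exact two-sided permutation p = 0.00794, the smallest possible, adjusted 0.0437 over 11 comparisons). The mitosis genes thus fell further, with a median change of -2.33 against -1.54. The 14 sterol genes (median -1.19, list adjusted p = 1.93e-14, and 0.0248 with an estimated correlation) and the 17 ribosome biogenesis genes (median -0.83, 2e-17, and 0.00462 with an estimated correlation) were all lower, over all genes and adjusted over the list alone. Idi1 changed by -2.54 ± 0.16 and Nop56 by -1.32 ± 0.08.

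Neuronal differentiation genes had 15 of 26 higher after multiple doses (15 adjusted over the list alone, median 0.59, list adjusted p = 3.38e-08). These, with Stmn2 at 1.65 ± 0.11, the neuronal tubulin Tubb3 at 1.34 ± 0.11 and Mapt at 1.58 ± 0.15, had an adjusted p = 0.0783 with an estimated correlation. Granule neuron progenitor genes had 8 of 17 higher and 2 lower (8 and 3 adjusted over the list alone; 0.0476), with Atoh1 at -0.60 ± 0.12, and had an adjusted p = 0.547 with an estimated correlation. The call was lost without vehicle replicate 1 (0.109), and 1 gene was lower without treated replicate 1 or 3 or vehicle replicate 2, 4 or 5. Hedgehog target genes had 9 of 17 lower and 1 higher (9 and 1 adjusted over the list alone; 8.44e-05), with Foxm1, a regulator of mitotic genes, at -2.30 ± 0.15. The list had an adjusted p = 0.0866 with an estimated correlation. Macrophage and microglia markers had 12 of 14 higher (12 adjusted over the list alone, median 1.65, 1.76e-05). They, with Cd68 at 2.10 ± 0.34, had an adjusted p = 0.524 with an estimated correlation. Fibroblast and matrix markers had 12 of 13 higher (13 adjusted over the list alone, median 1.34, 0.00015), and had an adjusted p = 0.547 with an estimated correlation. Endothelial markers had 7 of 12 higher (8 adjusted over the list alone; 0.0255), with an adjusted p = 0.705 with an estimated correlation. That call was lost without treated replicate 1 (0.0691). Muscle-rich arrays were 1 of 4 treated and 1 of 5 vehicle. With the muscle and fibroblast list means as covariates the macrophage and microglia markers had an adjusted p = 0.239 and the endothelial markers 0.953, the latter in the lower direction.

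The largest rises after multiple doses were in Scara5 (4.06 ± 0.69), Abca8a (3.66), the protease Mmp3 (3.49 ± 1.0), Ogn (3.38) and Slc40a1 (3.34 ± 0.39). They were followed by the matrix genes Lum (3.29) and Dcn (2.95 ± 0.63), Clec7a (3.25 ± 0.43), the chemokine Cxcl12 (3.0) and Gprin3 (2.95). The largest falls were in Wif1 (-4.70 ± 0.22, 26.0-fold), Cbln4 (-3.02), the histone gene H2ac11 (-3.01), Cldn2 (-2.96) and Pif1 (-2.90). Further falls were in Sowaha (-2.81), Doc2b (-2.73), Lama5 (-2.72) and Dcpp1 (-2.69). By the naming rule every treated array lay outside the vehicle range in each of these rises and falls. In all 8070 genes were called, 4258 higher and 3812 lower (52.8% higher, and 45% after a second quantile normalization), 1710 by 2-fold or more. Of the genes called at 24 h after a single dose 3098 were also higher here (751 by independent draws) and 2833 also lower (583 by independent draws), from arrays that share no sample. With 4 list means as covariates the rises of Scara5, Mmp3, Ogn and Cxcl12 were no longer called. The direction turned for Cxcl12 with 2 covariates (-0.0472) and 4 (-0.345) and for Mmp3 with 4 (-0.614). That fit holds no test of Lum and Dcn, which are members of a covariate list.

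The 40 mpk dose was compared with vehicle at the same times. At 6 h Gli1 was 9.31-fold lower, at 0.303 (n = 5) against 2.82 (n = 5), a change of -3.22 ± 0.19 (adjusted p = 1.39e-19). At 12 h it was 11.9-fold lower, at 0.217 (n = 3) against 2.57 (n = 4), a change of -3.57 ± 0.23 (8.28e-18). At 24 h it was 2.35-fold lower, at 0.978 (n = 4) against 2.30 (n = 5), a change of -1.23 ± 0.21 (3.06e-06). At 36 h it stood at 3.35 (n = 3) against 2.57 (n = 3), a difference of 0.38 ± 0.25 (0.572). Every treated array lay below every vehicle array at 6, 12 and 24 h. Ptch1 changed by -1.11, -1.40 and -0.74 at these 3 times, Hhip by -1.39, -1.38 and -1.15 and Ccnd1 by -0.58, -0.78 and -0.39. All were called and below vehicle in every treated array, though the 24 h call of Ccnd1 (adjusted p = 0.00771) was lost without treated replicate 4 (0.0883). Ccnd2 was higher at 24 h (0.75) and at 36 h (0.72 ± 0.14, adjusted p = 0.0014, and 0.0684 without treated replicate 1). Mycn was higher at 24 h (0.41 ± 0.10, adjusted p = 0.00109, all 4 arrays above vehicle). At 6 h the largest changes were in Robo2 (1.21), Dmrta1 (1.20), Igfbp5 (1.17), Cemip (1.04), Gdf10 (-2.37), Sox18 (-1.81) and Pdgfa (-1.71). At 12 h they were in Igfbp5 (1.90), Dmrta1 (1.60), Rec8 (1.48), Chrnb4 (1.42), Cxcl2 (-4.08 ± 1.30), Wif1 (-2.81) and Gdf10 (-2.51). Cxcl2, a chemokine with a vehicle SD of 4.5, lost its call without any 1 of the treated arrays (adjusted p = 0.103 to 0.117) or without vehicle replicate 3 (-2.39, adjusted p = 0.352) or 4 (0.153). The counts were 362 genes at 6 h (135 higher and 227 lower) and 1400 at 12 h (841 higher and 559 lower). The latter was 774 without treated replicate 1 and 915 without treated replicate 2.

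The gene groups at 40 mpk were those of the higher dose in part. G1/S genes had 2 of 25 lower at 6 h (7 adjusted over the list alone, list adjusted p = 4.36e-11), with an adjusted p = 0.132 with an estimated correlation. At 12 h 20 were lower (25 adjusted over the list alone, median -0.60, 4.74e-35, and 0.00507 with an estimated correlation), and at 24 h 24 were lower (24 adjusted over the list alone, median -0.91, 7.89e-27, and 0.00908 with an estimated correlation). The mean of the G1/S genes minus that of the G2/M genes differed by -0.38 at 6 h (exact two-sided permutation p = 0.00794, adjusted 0.0437 over 11 comparisons) and -0.74 at 12 h (exact p = 0.0286, adjusted 0.0449). At 6 h camera called the G2/M list higher (median 0.165, adjusted p = 4.43e-06), with 0 genes called by limma over all genes or adjusted over the list alone, and with an adjusted p = 0.405 with an estimated correlation. G2/M genes had 23 of 25 lower at 24 h (25 adjusted over the list alone, median -1.08, 8.35e-33, and 0.0135 with an estimated correlation), with Bub1 at -1.40 ± 0.11. Sterol synthesis genes had 14 of 14 lower at 24 h (14 adjusted over the list alone, median -1.10, 4.77e-23, and 0.00727 with an estimated correlation). At 36 h 12 of 14 were lower (14 adjusted over the list alone, median -0.98, 4.59e-38, and 0.000124 with an estimated correlation), and limma called 0 with only the groups compared at the same median. Camera also called host lists higher at 36 h, where limma called 0 of their genes. They were the macrophage (4 of 14 adjusted over the list alone, adjusted p = 1.01e-07), fibroblast (1 of 13 adjusted over the list alone, 0.000207), skeletal muscle (0.000226) and endothelial lists (0.00139). They had an adjusted p = 0.503, 0.503, 0.57 and 0.508 with an estimated correlation. The muscle call was lost without treated replicate 1 (0.0516) and the endothelial call with the muscle and fibroblast covariates (0.501). Msmo1 changed by -2.23 ± 0.16 at 24 h and -1.49 ± 0.19 at 36 h. Hedgehog target genes had 6 of 17 lower at 6 h and 7 at 12 h (8 and 8 adjusted over the list alone). The list held with an estimated correlation at both times (0.00574 and 0.0245) but not at 24 h (8 lower, 2 higher, both also adjusted over the list alone, adjusted p = 0.38 with an estimated correlation). Granule neuron progenitor genes had 4 of 17 higher at 6 h and 6 at 12 h (8 and 8 adjusted over the list alone; 0.0103 and 0.0268 with an estimated correlation). Neuronal differentiation genes had 11 of 26 higher at 12 h (15 adjusted over the list alone; 0.0268 with an estimated correlation). At 24 h 14 were higher (16 adjusted over the list alone; adjusted p = 0.266 with an estimated correlation), and 9 without treated replicate 4. Immediate early genes had 7 of 16 lower at 12 h (8 adjusted over the list alone, median -0.71, adjusted p = 0.109 with an estimated correlation), and 4 without vehicle replicate 3 or treated replicate 1. Hypoxia genes had 3 of 15 lower (9 adjusted over the list alone, median -0.37, adjusted p = 0.0721 with an estimated correlation), and 1 without vehicle replicate 3. At 12 h the granule neuron progenitor count was 3 without vehicle replicate 3 or treated replicate 1 or 2 and the neuronal count 7 without vehicle replicate 3. At 6 h the G1/S count was 0 without treated replicate 1 or 2, 4 without replicate 4 or 5, and 1 without vehicle replicate 3, 4 or 5. Macrophage markers had 10 of 14 higher at 24 h (12 adjusted over the list alone, median 1.10, adjusted p = 0.478 with an estimated correlation). Muscle-rich were 3 of the 4 treated and 1 of the 5 vehicle arrays. A fit without such arrays left 1 treated array and is not read as a test of the rise.

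At 24 h with 40 mpk 5728 genes were called, 3128 higher and 2600 lower (54.6% higher, and 40% after a second quantile normalization). Without the muscle-rich arrays 1 treated array was left. The spread in that fit came from other groups, so it is not read as a test. The muscle gene Myl2 (2.50 ± 0.58, and 1.49 without treated replicate 3), Pdk4 (3.01 ± 0.82), Scara5 (3.02 ± 0.69) and Aldh1a1 (2.44 ± 0.62) had the largest rises. In the 1 array left Pdk4 differed by 0.396, Scara5 by 1.41 and Aldh1a1 by 0.883. Wif1 (-3.41 ± 0.22), Dcpp1 (-2.62), Dcpp2 (-2.53) and Fdps (-2.26 ± 0.23) had the largest falls. At 36 h 146 genes were called, 62 higher and 84 lower (42.5% higher, and 28.3% after a second quantile normalization). Kcnj10 (1.52), Gprin3 (1.49), Vtn (1.38), Abcg1, a cholesterol exporter (1.38 ± 0.33), Dcpp2 (-2.06), Cbln4 (-1.80), Dcpp1 (-1.62) and Fdps (-1.62 ± 0.28) changed most. By the naming rule they lay outside the vehicle range in all 3 arrays. Leaving out vehicle replicate 1 or 3 gave 67 genes each, and leaving out treated replicate 1, 2 or 3 gave 45, 42 and 316. Muscle-rich were 2 of 3 treated and 0 of 3 vehicle arrays. A fit without such arrays left 1 treated array and is not read as a test of the changes. Kcnj10 lost its call without vehicle replicate 1 (adjusted p = 0.205) or treated replicate 1 (0.0745) or 2 (0.248), and Gprin3 without treated replicate 2 (0.0985). Vtn lost it without vehicle replicate 1 (0.101) or 3 (0.084) or treated replicate 1 (0.192) or 2 (0.124). Abcg1 lost it without vehicle replicate 1 (0.152) or 3 (0.223) or treated replicate 1 (0.0949) or 2 (0.264).

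The 2 doses were compared directly to ask what the higher dose added. At 24 h Gli1 was lower with 80 mpk than with 40 mpk, at 0.253 (n = 4) against 0.978 (n = 4), a difference of -1.95 ± 0.22 (adjusted p = 2.45e-08, all 4 arrays lower). Ptch1 differed by -0.65 ± 0.12 (0.000346, 3 of 4 arrays below every 40 mpk array) and Wif1 by -1.39 (0.000106). Ccnd1 differed by -0.49 ± 0.12 (0.0231), a call lost without replicate 1 (adjusted p = 0.158), 2 (0.0759) or 3 (0.107) of the 40 mpk arrays or replicate 1 (0.176) or 2 (0.131) of the 80 mpk arrays. Of the G1/S genes 17 of 25 were lower with the higher dose (23 adjusted over the list alone), and of the G2/M genes 15 of 25 (23 adjusted over the list alone). By limma 0 sterol synthesis genes and 0 macrophage markers differed. The G2/M count was 3 and 9 without replicates 1 and 2 of the 40 mpk arrays, and 3, 6 and 6 without replicates 1, 2 and 4 of the 80 mpk arrays. In all 260 genes differed at 24 h, 2 higher and 258 lower. By limma 0 were called with only the groups compared, where Gli1 had an adjusted p = 0.217. Other splits of the arrays do not exclude chance for this count, nor for those at 12 and 36 h. The count was 99 without replicate 1 of the 40 mpk arrays, 139 without replicate 1 and 150 without replicate 4 of the 80 mpk arrays. Gli1 differed by -0.78 ± 0.22 at 6 h (adjusted p = 1) and -0.91 ± 0.23 at 12 h (0.105), lower in every 80 mpk array than in any 40 mpk array at both times. limma called 0 genes at 1 h (739 at an unadjusted p under 0.05) and 0 at 6 h (785 at an unadjusted p under 0.05). At 12 h it called 13 (6 higher and 7 lower, 46.2% higher, and 71.4% after a second quantile normalization), among them Zbtb40 (-0.78, adjusted p = 0.00168) and Tmem248 (-0.47, 0.00169). The 12 h count was 0 to 7 without any 1 of the 40 mpk arrays or of replicates 1 to 3 at 80 mpk, and 200 without replicate 4 at 80 mpk. At 36 h 178 genes differed, 61 higher and 117 lower (34.3% higher, and 46.4% after a second quantile normalization). Among these 178 were Trp53inp1 (0.86, adjusted p = 0.000326), Stab2 (1.13, 0.00266) and the cell cycle gene Cdkn3 (-0.77, 0.00452). At 12 h and at 36 h limma called 0 genes with only the groups compared, and at 12 h 1 gene without the muscle-rich arrays. The count was 10 and 115 without replicates 1 and 3 at 40 mpk and 25, 456, 84 and 52 without replicates 1 to 4 at 80 mpk.

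Whether multiple doses acted differently from a single dose at 36 h was tested as a difference of effects. The effect on Gli1 was lower by -2.95 ± 0.31 after multiple doses (adjusted p = 9.96e-11) and on Ptch1 by -1.44 ± 0.17 (1.16e-09). It was lower on Hhip by -1.23 ± 0.36 (0.0194) and on Ccnd1 by -1.11 ± 0.18 (3.16e-06), while for Ccnd2 it differed by 0.03 (0.964). Of the G1/S genes 23 of 25 and of the G2/M genes 24 of 25 had a lower effect after multiple doses (23 and 24 adjusted over the list alone), as did 12 of 17 ribosome biogenesis genes (17 adjusted over the list alone). By limma 0 sterol synthesis genes and 0 macrophage markers differed in effect. In all 1564 genes differed, 409 higher and 1155 lower. The labels do not say whether the time runs from the first or the last of the multiple doses, so schedule and time since the last dose are not separated.

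The effects at 36 h and 12 h after a single dose of 80 mpk were compared in the same way. The effect on Gli1 was higher by 4.53 ± 0.32 at 36 h (adjusted p = 2.39e-16) and on Ptch1 by 1.30 ± 0.17 (1.92e-07). It was higher on Hhip by 1.39 ± 0.37 (0.0121), on Ccnd1 by 0.82 ± 0.18 (0.00228) and on Ccnd2 by 0.76 ± 0.18 (0.00384). Of the G1/S genes 11 of 25 had a higher effect at 36 h (13 adjusted over the list alone). Of the G2/M genes 9 of 25 a lower one (17 adjusted over the list alone, and 15 without treated 36 h replicate 2). Of the sterol synthesis genes 13 of 14 a lower one (14 adjusted over the list alone). In all 1340 genes differed, 703 higher and 637 lower (52.5% higher, and 35.4% after a second quantile normalization). The count was 838 without replicate 3 of the 12 h vehicle arrays, 723 without replicate 3 of the 36 h vehicle arrays and 858 without replicate 1 of the treated 36 h arrays.

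A single value per array, the mean log2 of Gli1, Ptch1, Hhip and Sfrp1, was compared by an exact two-sided permutation test. With 80 mpk it differed from vehicle by 0.11 at 1 h (exact p = 0.27, adjusted 0.371 over 11 comparisons), and by -1.81 at 6 h (exact p = 0.0179, adjusted 0.0394). It differed by -1.95 at 12 h (exact p = 0.0286, adjusted 0.0449), -1.47 at 24 h (exact p = 0.00794, adjusted 0.0218) and -0.03 at 36 h (exact p = 0.886, adjusted 0.886). With 40 mpk it differed by 0.14 at 1 h (exact p = 0.54, adjusted 0.594), -1.54 at 6 h (exact p = 0.00794, adjusted 0.0218), and -1.64 at 12 h (exact p = 0.0286, adjusted 0.0449). It differed by -0.73 at 24 h (exact p = 0.00794, adjusted 0.0218) and 0.23 at 36 h (exact p = 0.4, adjusted 0.489, where 3 against 3 arrays cannot give a p under 0.1). After multiple doses it differed by -1.39 at 36 h (exact p = 0.00794, adjusted 0.0218). The p-values at 6, 12 and 24 h and after multiple doses are the smallest these group sizes allow.

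Vehicle arrays were compared with each other to measure time and schedule without the compound. Across the 5 single-dose times 1354 genes differed by the moderated F test of limma. Among 17 clock genes 7 differed (9 adjusted over the list alone). Nr1d1, a repressor in the circadian clock, stood at -1.41 at 12 h and -2.53 at 36 h (mean log2 level, a 2.17-fold range, adjusted p = 0.00204), and Dbp had a 1.89-fold range (0.00194). The others were Cry2, Clock, Per1, Per2 and Bhlhe40, with ranges of 0.31 to 0.59 on the log2 scale. Like Nr1d1, Dbp was higher at 12 h (-1.44) than at 36 h (-2.30). These labels lie a day apart, so the differences in clock genes are not read as a daily rhythm. The SD of both genes was widest at 12 h (0.37 for Nr1d1 and 0.47 for Dbp). Sterol synthesis genes also moved with time in vehicle arrays (10 of 14, and 14 adjusted over the list alone), hedgehog target genes did not (0 of 17). The smallest adjusted p-values belonged to Fer and Ndufv3 (8.22e-05 each), Sqstm1 (9.37e-05), Nmnat1 (0.000334) and the histone gene H3c7 (0.000369). Leaving out single arrays gave 808 and 554 genes without replicates 2 and 5 at 6 h. It gave 710 and 732 without replicates 3 and 4 at 12 h, 676 without replicate 4 at 24 h and 832 without replicate 3 at 36 h.

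Multiple and single dosing with vehicle differed in 1188 genes at 24 h, 736 higher and 452 lower with multiple doses (62% higher, and 36.9% after a second quantile normalization). Flt1, a receptor of vascular endothelial growth factor, was higher by 1.01 ± 0.18, Mgll by 0.84, Cspg4 by 0.67, Ctdspl by 0.55 and Ccser2 by 0.51 (log2 differences, adjusted p = 0.00172 each, n = 4 and 5). Of the clock genes Per1 was higher by 0.62 (0.00963), Cry2 by 0.41 (0.0114) and Nfil3 by 0.67 (0.0132). Endothelial markers had 5 of 12 higher (1 to 3 without single-dose replicate 2, 3, 4 or 5 or multiple-dose replicate 1, 2 or 3). Adipocyte markers had 2 of 9 higher (median 1.94) and pericyte and smooth muscle markers 2 of 10 (median 0.58), and Retn, a fat cell gene, was higher by 2.51 ± 0.77 (0.0431). Both counts were 0 without single-dose replicate 3 or 4 or multiple-dose replicate 2 or 3, and 7 and 4 without multiple-dose replicate 4. Glucocorticoid response genes had 4 of 12 higher (2 without single-dose replicate 1, 3 or 4 and 0 without multiple-dose replicate 2). Gli1 differed by 0.11 (0.805). The 24 h count was 473, 238 and 555 without replicates 3, 4 and 5 of the single-dose arrays and 550, 76 and 546 without replicates 1, 2 and 3 of the multiple-dose arrays. At 36 h 6 genes were called, all higher, among them H3c7 (1.81 ± 0.25, adjusted p = 1.34e-05), H1f4 (0.74), Rfx3 (0.72) and Cep43 (0.42, 0.0321 each). The count was 1 or 2 without any 1 array except replicate 2 of the multiple-dose arrays, without which 156 were called.

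The multiple-dose group of 80 mpk at 24 h held 1 array and was not tested. Its Gli1 level lay 23.5-fold below the mean of 4 vehicle arrays (a log2 difference of -4.55), Ptch1 differed by -1.87, Ccnd1 by -0.93, Hhip by -1.03 and Ccnd2 by 1.12. The list medians were -1.70 for G1/S genes, -1.74 for G2/M genes, -1.20 for sterol synthesis genes, 0.91 for macrophage markers and 0.68 for neuronal differentiation genes. Among 10000 random lists matched on mean level the first 3 medians were at percentile 0 and the last 2 at percentile 100. Random lists do not allow for genes that move together, so these percentiles are not a test of treatment. The largest differences in named genes were in Slc40a1 (3.87), Adamdec1 (2.64), Rec8 (2.55), Kcnj10 (2.52) and Wif1 (-4.51). They were also large in Cd72 (-3.67) and Saa3 (-3.45), whose vehicle SD was 2.5 and 2.9.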

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

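Of the tests in this part, those of sterol genes at 40 mpk, of smooth muscle markers and of fibroblast markers were chosen only after the result was seen.

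The effect of 80 mpk on Gli1 at 36 h was lower by -2.95 after multiple doses than after a single dose, on Ptch1 by -1.44 and on Hhip by -1.23, and 1564 genes differed in effect by the interaction test of limma. Between 36 h and 12 h after a single dose the effect on Gli1 differed by 4.53, on Ptch1 by 1.30 and on Hhip by 1.39, and 1340 genes differed.

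Some arrays lay far from the others of their group. Gli1 was 1.40 (log2 intensity) in vehicle replicate 2 at 36 h of multiple dosing, against 1.74 to 1.86 in the others. The mean of the keratinocyte and skin genes was -2.29 in vehicle replicate 3 at 12 h (others -3.88 to -3.75), -3.27 in 80 mpk replicate 1 at 24 h (others -3.89 to -3.83) and -1.36 in replicate 1 of multiple 80 mpk doses at 36 h (others -3.87 to -3.50). The mean of the neutrophil genes was -0.27 in 40 mpk replicate 3 at 1 h (others -3.60 to -3.41), -0.95 in 80 mpk replicate 4 at 1 h (others -3.52 to -3.02) and -3.02 in vehicle replicate 1 at 24 h (others -3.62 to -3.51). Vehicle replicate 1 at 24 h also had a macrophage list mean of 2.0 (others 1.05 to 1.29), and 40 mpk replicate 3 at 6 h had a sterol list mean of 0.67 (others 0.88 to 0.96). Chance alone places about 1 in 20 groups past this limit, which gives 4.9 of the 98 tests, and 9 were found.

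Sterol synthesis genes were lower at 36 h after a single dose although Gli1 was back near its vehicle level. High vehicle arrays at 36 h as the whole cause are argued against by the vehicle arrays of 12 h, against which 13 of 14 genes were lower (median -0.82), and more host tissue by 14 of 14 genes lower with 4 list means as covariates (median -1.08). Hedgehog target output at the time of sampling is argued against by 40 mpk at 36 h, where 12 of 14 were lower and Gli1 differed by 0.38 (adjusted p = 0.572), although 7 of 14 were lower against the vehicle arrays of 12 h (median -0.48) and limma called 0 with only the groups compared, 3 against 3 arrays at the same median of -0.98. Excess sterol would also turn on liver X receptor targets. Of these 2 of 7 were higher at 36 h with the macrophage list mean as a covariate (Pltp 0.60 ± 0.12 and Apoe 0.87 ± 0.22). Without it 3 of 7 were higher (Smpdl3a 1.43 ± 0.49, Pltp 1.16 ± 0.19 and Apoe 2.41 ± 0.47). Srebf1 was lower in both fits (-0.68 ± 0.14 and -0.77 ± 0.13) and Nr1h3 only with the covariate (-0.63 ± 0.19 against 0.38 ± 0.33). The bound of more than 3 was not met. This does not settle excess sterol at 36 h, since the 7 left out the cholesterol exporters Abca1 and Abcg1 and the covariate lowered the rise of Apoe. Abcg1 was higher at 40 mpk and 36 h (1.38), a call lost without some single arrays. Excess sterol at an earlier time stays open as well. Without the covariate Lpcat3, Nr1h3 (1.22 ± 0.29), Smpdl3a (1.98 ± 0.43), Pltp and Apoe of the 7 were higher at 24 h, as was Abca1. In the same fit Srebf1 was lower (-0.41 ± 0.11) and Scd1 was not called. A candidate explanation by a slower effect of treatment that outlasts the change in Gli1 also stays open.

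Macrophage markers were higher at 24 h and after multiple doses, and fibroblast markers with them. Muscle taken with the tumour is argued against as the whole cause of the macrophage rise at 24 h. Without the muscle-rich arrays 8 of 14 markers were still higher (median 1.31, and 1.26 with them). That fit left out 2 of the 4 treated and 1 of the 5 vehicle arrays, so it rests on few samples and draws much of its spread from other groups. Other neighbouring tissue stays open. In that fit fibroblast (2 of 13 called, median 0.98) and endothelial markers (5 of 12 called, median 0.87) also remained higher. With the muscle and fibroblast covariates camera did not call the macrophage list at 24 h (adjusted p = 0.0506) or after multiple doses (0.239). A lower tumour share that raises every other cell type alike is not settled after multiple doses. There the macrophage mean minus that of the pericyte and smooth muscle markers was 4.15 (SD 0.36) against 2.9 (SD 0.31) in vehicle arrays. This did not pass (exact two-sided permutation p = 0.00794, the smallest possible, adjusted 0.0873 over 11 comparisons). In a test chosen after the result was seen, 2 pericyte and smooth muscle markers were lower, Tagln (-0.93 ± 0.20) and Acta2 (-0.75 ± 0.26). Against that, Rgs5 (1.57 ± 0.26), Pdgfrb (0.73 ± 0.26), Abcc9 (0.64 ± 0.26) and Notch3 (0.46 ± 0.18) were higher. For fibroblast markers at 24 h, treatment and neighbouring tissue cannot be told apart, since 2 of 13 were called without the muscle-rich arrays at a median of 0.98 (1.11 with them) and fewer arrays widened the error. More macrophages, or more of their transcripts, in treated tumours may explain the first pattern and was not tested separately.

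Hypoxia and immediate early genes were lower at 12 h, where vehicle replicate 3 stood apart. Unusual vehicle arrays at 12 h as the whole cause are argued against by the vehicle arrays of 6 h, against which 13 of 31 genes were lower at 80 mpk (18 against the 12 h arrays). Between the 2 vehicle groups the list medians differed by 0.06 and 0.15. There limma called 0 genes of the 2 lists, which decides little, since Dusp1 at 0.98 ± 0.28 was not called either (adjusted p = 0.888). Across all vehicle times 10 of 15 hypoxia and 8 of 16 immediate early genes differed by the F test adjusted over the list alone (1 and 3 over all genes). The 6 h arrays are therefore not matched in time. With 40 mpk 5 were lower against the 6 h vehicle arrays. The bound written for that test before the result was seen did not allow for 3 arrays and a lower dose, with medians of -0.29 and -0.39 against -0.41 and -0.53 at 80 mpk, so treatment itself and other causes cannot be told apart at that dose.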

How the results depend on the processing

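Of the alternatives in this part, 4 list means as covariates and leaving out the muscle-rich arrays were chosen only after the data were seen. Each count below is a number of called genes. Of 21 counts, those within 1.5 times the reported value numbered 21 with a trend and robust prior, 20 with a filter on dim genes, 20 with a replicate block, 19 with the mean of all probes, 19 with a second quantile normalization, 16 with the muscle and fibroblast covariates, 14 with 4 covariates, 10 with array weights, 9 without the muscle-rich arrays and 8 with only the groups compared. Of 153 called values of named genes 125 to 152 were still called under each of these settings, and 1230 of 1272 when single arrays were left out.

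Array weights gave 2 genes for 80 mpk at 1 h, 607 at 6 h and 3957 at 36 h, 2353 for 40 mpk at 12 h and 350 at 36 h, 1 for 80 against 40 mpk at 6 h, 1616 at 12 h and 534 at 24 h, 3728 and 106 for vehicle schedules at 24 and 36 h, and 3072 across vehicle times. The cause was not tested.

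Without the muscle-rich arrays the counts were 100, 1379 and 1186 for 80 mpk at 6, 12 and 36 h, 738, 1720 and 0 for 40 mpk at 12, 24 and 36 h, 1, 25 and 1 for 80 against 40 mpk at 12, 24 and 36 h, 664 for the effect at 36 h minus 12 h, 1 for vehicle schedules at 36 h and 577 across vehicle times. With only the groups compared they were 110, 1007 and 859 for 80 mpk at 6, 12 and 36 h, 172, 655 and 0 for 40 mpk at 6, 12 and 36 h, 0, 0 and 0 for 80 against 40 mpk at 12, 24 and 36 h, 845 for multiple minus single doses, 628 for 36 h minus 12 h, and 1960 and 1 for vehicle schedules at 24 and 36 h. Both settings use fewer samples by construction. Leaving out the muscle-rich arrays left 1 treated array for 80 mpk at 6 h and for 40 mpk at 24 h and 36 h, so there the spread came from the other groups, and the falls of these counts and of 80 against 40 mpk at 24 h and 36 h say nothing about tissue.

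The muscle and fibroblast covariates gave 1 gene for 40 mpk at 1 h and 264 at 36 h, and 1, 49 and 491 for 80 against 40 mpk at 6, 12 and 36 h. The 4 covariates gave 1, 589 and 276 for 40 mpk at 1, 6 and 36 h, 1, 70 and 420 for 80 against 40 mpk at the same 3 times as above, and 10 for vehicle schedules at 36 h. The mean of all probes and a second quantile normalization each gave 7 for 80 against 40 mpk at 12 h, and 19 and 3 for vehicle schedules at 36 h, where the replicate block gave 1. The filter on dim genes gave 297 for 80 against 40 mpk at 36 h. The cause was not tested. After multiple doses Mycn was 0.00208 and 0.0609 with 2 and 4 covariates, Cxcl12 -0.0472 and -0.345, and Mmp3 -0.614 with 4, each reversed from the reported direction.

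Leaving out single arrays gave 0 to 1 genes for 80 mpk at 1 h, 236 to 371 at 6 h and 1275 to 2740 at 36 h. For 40 mpk the range was 0 to 43 at 1 h, 774 to 1473 at 12 h and 42 to 316 at 36 h. For 80 against 40 mpk it was 0 to 200 at 12 h, 99 to 334 at 24 h and 10 to 456 at 36 h, and for the effect at 36 h minus 12 h 723 to 1604. Vehicle schedules gave 76 to 1562 at 24 h and 1 to 156 at 36 h, and vehicle times 554 to 2005. The report names the arrays behind the large moves. The hedgehog target mean ranged from -1.879 to -1.733 for 80 mpk at 6 h, from -2.001 to -1.867 at 12 h and from -1.686 to -1.552 for 40 mpk at 12 h, and its adjusted p rose to 0.0748, 0.0524 and 0.157, where fewer arrays raise the smallest p that permutation can give.

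Of the 103 list calls 28 held with an estimated correlation, 75 with the fry test, 77 with the muscle and fibroblast covariates, 69 with 4 covariates, 80 without the muscle-rich arrays, 92 with the filter on dim genes and 100 or 101 under each of the other 4 settings run for lists. The interferon response genes at 80 mpk and 36 h were called higher by camera (adjusted p = 0.0275) and with 4 covariates lower (0.0276). The higher call was lost with the fry test (0.339). In camera it was lost with the filter on dim genes (0.0575) and with the muscle and fibroblast covariates (0.635). Of the 12 list calls in that comparison only that of the sterol genes held with an estimated correlation. The covariates are the means of the muscle and fibroblast lists, and of the macrophage and keratinocyte lists where there are 4, and the muscle-rich arrays were chosen by the muscle list. A lost or turned call of such a list in its own setting is fixed by construction and says nothing. Other calls that turned direction and were then not called were those of the endothelial markers after multiple doses with 2 and 4 covariates (0.953 and 0.781) and at 40 mpk and 1 h without treated replicate 3 (0.746), and of the fibroblast markers at 40 mpk and 24 h without the muscle-rich arrays (0.796), where 1 treated array was left. Without the same replicate 3 at 1 h the macrophage and fibroblast lists were called lower (0.00598 and 0.00727). Replicate number was not used as a pairing in the reported fit, since in no comparison did every pair of the same number correlate above 0.1. Mean correlations of such pairs ran from -0.27 (40 mpk at 1 h) to 0.134 (80 mpk at 24 h), and 1 pair reached 0.504 (80 mpk at 1 h). This does not show that the samples were unpaired, and the labels do not settle it.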

Other observations

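All 6 genes of the next paragraph were singled out after their values were seen, and the tests on other splits of the samples were planned.

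Hes5, which keeps neural progenitors undifferentiated, differed by -0.96 at 12 h, -1.41 at 24 h and -1.83 at 36 h after a single dose and by -2.62 after multiple doses, while Hey1 was higher by 1.08 at 12 h and 0.94 at 24 h. They are 2 of the 14 Notch and Wnt target genes, a list that camera called for 80 mpk only at 36 h (1 lower, 1 adjusted over the list alone, adjusted p = 0.0422), with an adjusted p = 0.166 with an estimated correlation and 0.119 with 4 covariates. That call was lost without vehicle replicate 1 (0.0697) or 2 (0.0845) or treated replicate 2 (0.0756), 3 (0.0535) or 4 (0.0636). Olig1, a transcription factor of the oligodendrocyte lineage, fell with the hedgehog targets (-1.06 at 6 h, -1.60 at 12 h and -1.88 at 24 h) and differed by -0.62 at 36 h without passing the test. Hlf, a clock output gene, was lower by -1.16 at 12 h and -1.13 at 24 h. Ddit4 was higher by 1.04 at 6 h and 1.21 at 24 h and lower by -1.01 at 36 h. Hk2 was lower by -1.78 at 24 h and by -1.81 after multiple doses and differed by -0.28 at 36 h after a single dose.

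Other splits of the same arrays into groups of the same sizes were refitted to ask whether chance can be excluded. For 80 mpk against vehicle 1 of 56 splits called as many genes at 6 h (378, highest other 218), 1 of 35 at 12 h (2120, highest other 462), 1 of 100 at 24 h (7095, highest other 5853) and 1 of 35 at 36 h (2341, highest other 2074), the real split included. For 40 mpk it was 1 of 100 at 6 h (362, highest other 109), 1 of 35 at 12 h (1400, highest other 944) and 1 of 100 at 24 h (5728, highest other 4405), and for multiple doses 1 of 100 (8070, highest other 7106). Each share is under 0.05 and the smallest its number of splits allows, without adjustment over the comparisons. The real split thus ranked first in each, which does not by itself exclude chance. At 36 h with 80 mpk another split came near the real count. At 40 mpk and 36 h the 10 splits are too few for a share under 0.05 (146, highest other 0).

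Where the real split called 0 genes every split called as many by construction, so the splits decided nothing. This holds at 1 h with 100 of 100 splits for 80 mpk (0, highest other 1) and for 40 mpk (0, highest other 456), where a split that called 456 points to a structure of the samples. It also holds between the 2 doses with 100 of 100 splits at 1 h (0, highest other 4) and 56 of 56 at 6 h (0, highest other 4). Between the doses chance is not excluded at the later times, with 2 of 35 at 12 h (13, highest other 284), 2 of 35 at 24 h (260, highest other 265) and 2 of 35 at 36 h (178, highest other 344). The 284 genes at 12 h point to a structure of the samples. For multiple minus single doses 4 of 100 splits called as many genes (1564, highest other 4701), and for 36 h minus 12 h 4 of 100 (1340, highest other 2030). Both shares are under 0.05, but some other splits called more genes than the real one, so chance is not settled for these counts. The split with 4701 also points to a structure of the samples. For vehicle arrays the real split ranked first for the schedules at 24 h, with 1 of 100 (1188, highest other 20). The same was so for the times, with 1 of 100 (1354, highest other 514). The 24 h count fell to 76 without multiple-dose replicate 2, and the count across times to 554 without replicate 5 at 6 h. For the schedules at 36 h chance is not excluded, with 4 of 56 (6, highest other 41). The 41 genes also point to a structure of the samples.

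The multiple-dose array of 80 mpk at 24 h also differed from vehicle by a list median of -0.50 for hypoxia genes and -1.51 for skeletal muscle genes, both at percentile 0 of random lists. Of the 4 vehicle arrays 1 was muscle-rich and the treated array was not, so the muscle difference cannot be told apart from tissue taken with the tumour. Random lists do not allow for genes that move together, so neither percentile is a test of treatment.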
